A study of Mus musculus with 8 samples.

How the data were processed

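Messenger RNA was measured by sequencing in muscle stem cells (satellite cells, the resident stem cells of skeletal muscle) of 8 male C57BL/6 mice, 4 young animals aged 4 months and 4 old animals aged 22 months, with 1 library per animal. Per the labels' protocols, cells of the limb muscles were sorted by flow cytometry as negative for CD45 (leukocytes), CD31 (endothelium) and Sca1 (fibro-adipogenic and other cells) and positive for VCAM, and were frozen without culture. ERCC spike-in RNA was added in proportion to cell number, 10 µl of a diluted stock for 122000 cells, and 10 ng of RNA entered oligo(dT)-primed cDNA synthesis with the SMARTer system, per the labels' protocols. Sheared cDNA was amplified for 6 to 9 cycles and sequenced in 101-base paired reads on a HiSeq 2000, and the labels state 26 to 37 M reads (M, the SI prefix mega) per library. A kit of this kind does not mark the strand, so reads of overlapping antisense genes cannot be told apart.

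The authors deposited a single table of 24630 genes by 8 libraries, in RPKM (reads per kilobase of gene and per M reads). Per the submitters' processing notes, the authors used Trim Galore, STAR, featureCounts, Subread and edgeR with the builds mm10 and GRCm38. Versions, settings and annotation are not given in the sources used here. The values themselves were tested for how they were made. In 100% of the 24630 genes they were whole multiples of the worth of 1 read, with a largest distance of 0.000452 from a whole number against an allowed 0.03, so reads per gene were recovered. The recovery returned the drawn reads, or these up to a common divisor, for 100% of 23224 simulated genes. The library sizes behind the RPKM values differed by at most 0.0332% from trimmed-mean (TMM) library sizes computed over all genes of the table. For 81.2% of 23198 genes the implied length equalled the merged exon length in GENCODE M21 on GRCm38, the annotation from which coordinates are taken here. In 8293 genes zeros had been replaced by a small positive value, and 1169 genes had no read in any library. The table had 58 genes with a repeated symbol, and 0 genes were ERCC sequences, so the spike-in comparison and the scaling per cell that it would give are not analysed here.

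The recovered reads gave the depth, which here means reads in genes. The labels state 26 to 37 M reads per library, so fewer reads in genes need not mean fewer reads sequenced. What became of the other reads is not known from the sources used here, and thinning of reads tests only their number. The 4 young libraries held 2.69, 1.91, 6.56 and 5.69 M reads in genes and the 4 old libraries 20.1, 24.9, 22.9 and 20.8 M. A count of 3 reads in a gene of 1 kb corresponded to 0.403 to 0.959 RPKM in the young libraries and to 0.157 to 0.181 RPKM in the old. These floors cover counting error only, because amplified reads are not independent molecules. All 4 libraries with the fewest reads were young, so depth and age cannot be separated by a comparison within depth.

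The design fixed before the data were examined foresaw a quasi-likelihood test of counts, or limma on a log scale if the values were not counts. The table holds RPKM, so the test was limma-trend (limma 3.58.1, R 4.3.3) on log2(RPKM + 1), old against young, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of genes with low values. Genes with a mean RPKM of at least 5 were tested, 5703 in all. This filter was chosen after seeing the data, and the number of lower genes depends strongly on it. The same model was run on values scaled by library totals, an alternative fixed before the data were examined. It is given throughout because the median log2 fold change of all tested genes was 0.64 on the deposited scale. In the text, "rose" is used for genes past the threshold on both scales and "fell" for genes past it on library totals, where a change is a change in the share of reads. Fitting these models to simulated reads of 5703 genes on the library-total scale, with 50 genes changed at each size, recovered 64% of 1.5-fold, 96% of 2-fold, 100% of 3-fold and 100% of 4-fold changes. In that test 15 unchanged genes were called, 7.69% of the calls.

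Gene lists were fixed before the data were examined, 40 in number, and 38 had at least 3 measured members. Each was tested with camera (limma) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 38 lists, and again with the correlation estimated from the data and with fry. Summed markers of 9 other cell types, in CPM, were compared by an exact two-sided permutation test over 70 assignments. CPM are counts per M of the library size of the deposited scaling, not of the reads, unless library totals are named. The named genes were chosen by a rule fixed beforehand. It took the 10 higher and the 10 lower genes with the largest change on the deposited scale among those past the threshold with a mean log2 CPM of at least 3, no overlap between the groups and a regular symbol, then the preset genes, then up to 3 members per described list with the smallest p. Described lists were those called on either scale, those of other cell types and the list of muscle stem cell identity. Up to 2 members per list with the smallest p on library totals were added after their values were seen, because the deposited-scale p favours members that rose, as were 4 members with large falls that are named as such. Of the list members the rule picks, 3 are not reported here.

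Alternatives covered scaling, filter, pseudocount, test, library weights, subtraction of low-level signal, thinning of reads, a replicate block and leaving out each library. Quasi-likelihood and negative-binomial count tests were not run, because the deposited unit is RPKM. Reactome gene sets from fgsea 1.28.0 and a family of ribosome assembly genes were examined only after the data were seen.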

Results

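Quiescent muscle stem cells of young (4 months, n = 4) and old (22 months, n = 4) male mice were compared by RNA sequencing, with each library made from a single animal. The design asks which transcripts differ with age in these cells before they are activated. The deposited table gives RPKM for 24630 genes, and 5703 genes with a mean of at least 5 RPKM were tested with limma.

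The libraries differed in depth and in low-level signal. Reads in genes ranged from 1.91 to 6.56 M in the young libraries and from 20.1 to 24.9 M in the old. Genes of families that are silent in muscle, such as olfactory and vomeronasal receptors (1541 genes), took 0.194% ± 0.137 of the reads in young (SD, n = 4) and 0.0109% ± 0.00400 in old libraries (SD, n = 4). Their mean value was 0.348 ± 0.169 RPKM in young and 0.0347 ± 0.0109 RPKM in old libraries. The library size used by the deposited scaling was 1.29 ± 0.236 times the reads in young and 0.789 ± 0.0776 times the reads in old libraries, so that expressed genes stand higher in old animals on the deposited scale than as a share of reads.

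**Figure D1:**
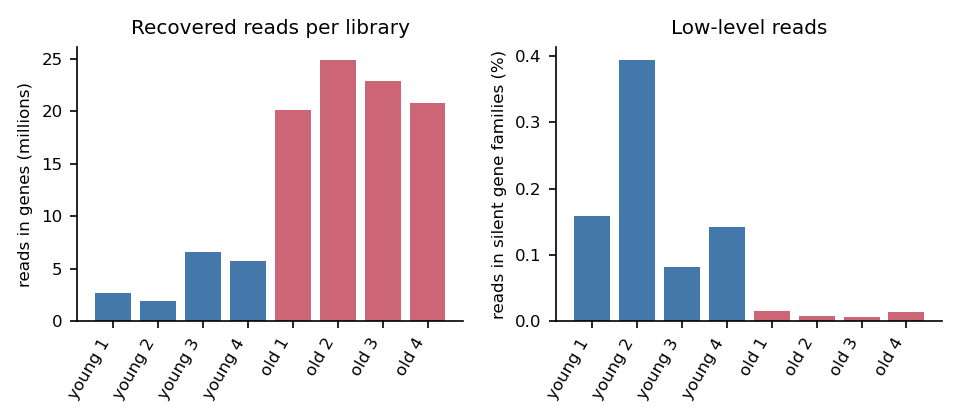
Bars show, for each of the 8 libraries, the recovered reads in genes (left, M reads) and the percent of those reads in silent gene families (right), in blue for young and red for old. The old libraries hold 20.1 to 24.9 M reads and at most 0.0148% of low-level reads, and the young libraries 1.91 to 6.56 M reads and at least 0.0816%.

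In muscle stem cells of old mice (n = 4) the retinoic acid-degrading enzyme Cyp26a1, the matrix protease Mmp3 and the haem-degrading enzyme Hmox1 made up a larger share of reads than in young mice (n = 4). Their log2 fold changes were 3.32 ± 0.35, 2.54 ± 0.29 and 2.13 ± 0.23 (SE). The calcitonin receptor Calcr, which holds these cells in quiescence, and the collagen Col3a1 made up a smaller share, with -1.52 ± 0.16 and -1.75 ± 0.16. Interferon-stimulated genes ranked higher in old cells (camera, adjusted p = 0.000266, and adjusted p = 0.65 with an estimated correlation). Immediate early genes, which dissociation and activation induce, ranked lower (adjusted p = 2.13e-07, and adjusted p = 0.65 with an estimated correlation). On library totals 700 genes rose, 722 fell and 4281 were not called.

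On the deposited scale 3946 of the 5703 genes passed (limma, Benjamini-Hochberg adjusted p under 0.05), 3882 higher and 64 lower in old animals, which is 98.4% higher. The median log2 fold change of all tested genes was 0.64 on that scale and -0.01 on library totals, where 49.2% of the 1422 called genes were higher. All 700 genes higher on library totals also passed on the deposited scale, and 58 of the 722 lower genes did. On the deposited scale the values of the 4 old libraries did not overlap those of the 4 young for 3489 higher and 27 lower genes. This is 61.7% of those tested, where chance gives 2.86%, and it holds the shift of 0.64, so it is not a measure of change as a share of reads. Fold changes below are on library totals unless stated, with the standard error, and are thereby relative to the shift of 0.64. RPKM values are as deposited, so they hold that shift, and their ratios are not the fold changes on library totals. The number of lower genes on the deposited scale depended on the filter, with 592 at a mean of at least 1 RPKM, 24 at 10 RPKM and 6908 without a filter, and it was 129 without young library 2 and 122 without young libraries 1 and 2.

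**Figure D2:**
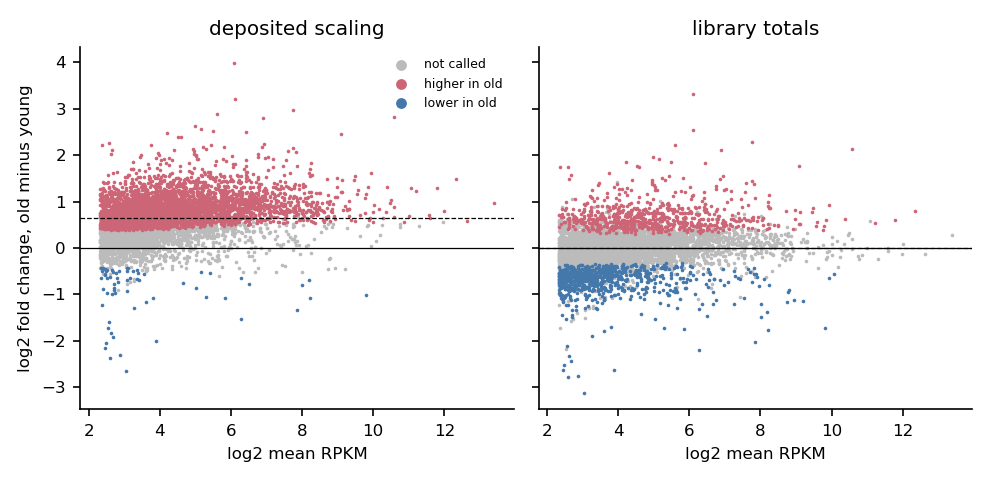
Each point is 1 of the 5703 tested genes, with log2 mean RPKM on the x axis and the log2 fold change, old minus young, on the y axis, for the deposited scaling (left) and library totals (right). The dashed line marks the median, 0.64 on the left and -0.01 on the right, and the called genes are 3882 higher and 64 lower on the left and 700 higher and 722 lower on the right.

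Among the 10 higher genes with the largest change that the rule named, Cyp26a1 (chromosome 19, 37697798 to 37701536, plus strand) stood at 128 ± 17.8 RPKM in old and 7.99 ± 4.17 RPKM in young animals (SD, n = 4 each). This is a log2 fold change of 3.32 ± 0.35 (limma, adjusted p = 0.000292) on library totals and 3.97 ± 0.27 on the deposited scale. Mmp3, or stromelysin, rose by 2.54 ± 0.29 on library totals (adjusted p = 0.000362) and had 126 ± 44.3 deposited RPKM in old and 12.1 ± 1.70 in young animals (3.21 on the deposited scale). Hmox1 (chromosome 8, 75093621 to 75100589, plus strand) reached 2697 ± 1300 RPKM in old against 365 ± 110 RPKM in young animals. The secreted proteins Angptl7, Thbs4 and Serpina3n rose by 2.29, 2.12 and 1.91 on the log2 scale. Thbs4 is also a tenocyte marker, and 6 of 7 such markers rose in the same libraries (median 1.55). Among the old libraries, library 2 had the lowest tenocyte sum (3863 CPM), which includes Thbs4. It also had the lowest old values of Angptl7 (151 RPKM), Thbs4 (127 RPKM) and Mmp3 (72.5 RPKM). Old library 2 was likewise lowest for the fibroblast (6409), pericyte (1472), muscle fibre (509) and erythroid (49.6 CPM) sums. For the endothelial sum it was highest (2064 CPM), and it was not lowest for leukocyte, lymphocyte or Schwann markers. Old library 3 had a tenocyte sum of 4146 CPM, and its Angptl7 lay within 455 to 475 RPKM. Dio2, which activates thyroid hormone, rose by 2.22 ± 0.15, the ubiquitin ligase Rnf180 by 1.97 ± 0.19, the endocytic adaptor Dab2 by 1.84 ± 0.12 and Il33 by 1.83 ± 0.17. All 10 kept adjusted p-values of at most 0.00265 on library totals.

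Among the 10 lower genes with the largest change that the rule named, Popdc2, a membrane protein of striated muscle, stood at 5.02 ± 0.406 RPKM in old and 14.3 ± 5.10 RPKM in young animals, with a log2 fold change of -1.89 ± 0.17 on library totals (limma, adjusted p = 0.000204) and -1.29 on the deposited scale. Mest changed by -1.78 ± 0.20, and Col3a1 (chromosome 1, 45311538 to 45349706, plus strand) by -1.75 ± 0.16 on library totals and -1.07 on the deposited scale, where it had 36.1 ± 3.49 RPKM in old and 78.1 ± 17.8 in young animals. Calcr, the calcitonin receptor, lay at 22.5 ± 2.88 RPKM in old and 42.5 ± 11.7 RPKM in young animals, with a log2 fold change of -1.52 ± 0.16 on library totals and -0.85 ± 0.22 on the deposited scale. Col15a1 changed by -1.33 ± 0.14, Vstm4 by -1.48 ± 0.16 and the mitochondrial isocitrate dehydrogenase Idh2 by -1.43 ± 0.15. The linker histone gene Hist1h1c (-1.44), the transcription factor Nfic (-1.31) and the tubulin Tubb4a (-1.29) completed the group. Histone transcripts mostly lack poly(A) tails, so oligo(dT) priming measures them poorly.

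**Figure D3:**
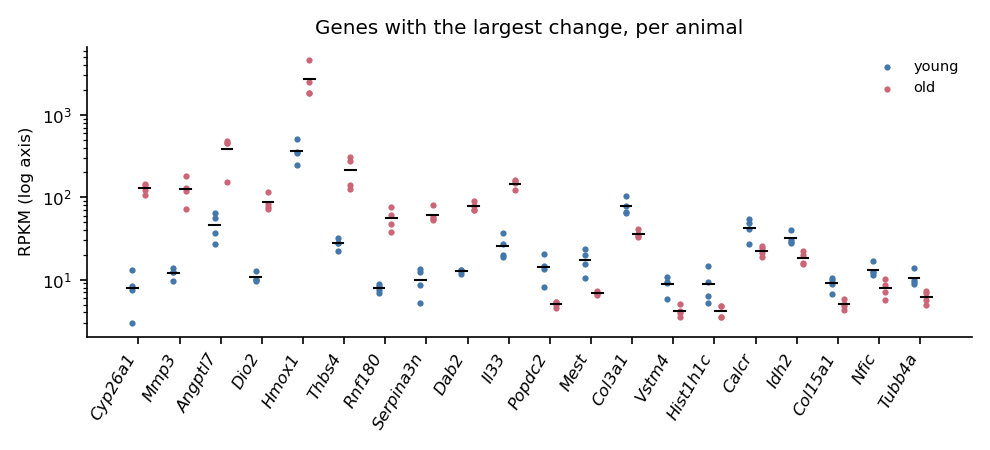
Points give RPKM on a log axis for each animal, young in blue and old in red, with the mean as a bar, for the 10 higher and the 10 lower genes that the rule named by their change on the deposited scale. The rule asked for no overlap between groups, so the 4 old animals lie above the 4 young for each of the first 10 genes. An example is Cyp26a1 at 106 to 143 against 2.95 to 13.1 RPKM. By the same rule the old animals lie below the young for the others.

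Of the genes named in advance, the satellite cell factor Pax7 fell as a share of reads by 0.68 ± 0.18 on the log2 scale (limma, adjusted p = 0.0166). Its deposited values were 13.5 ± 2.06 RPKM in old and 14.1 ± 4.28 RPKM in young animals (log2 fold change -0.03, adjusted p = 0.895). Without old library 4 the adjusted p of Pax7 on library totals was 0.0525. The myogenic factor Myod1 rose by 0.78 ± 0.16 on library totals and 1.47 on the deposited scale, where it had 1030 ± 193 RPKM in old and 368 ± 42.9 in young animals. Vcam1, the marker of the sort, rose by 0.79 ± 0.20 and 1.49 on these scales, with 613 ± 213 and 221 ± 82.3 deposited RPKM. Without young libraries 1 and 2 Vcam1 was not called on library totals (adjusted p = 0.110). Myf5 was higher in old animals on the deposited scale (log2 fold change 0.95, adjusted p = 0.00151) and not called on library totals (0.25 ± 0.15, adjusted p = 0.233). Spry1, an inhibitor of growth factor signalling, had a log2 fold change of 0.39 on the deposited scale and -0.30 on library totals, and the cell cycle inhibitor Cdkn1a 0.45 and -0.23, with no call on either scale. Cyclin D1 (Ccnd1) lay below the filter. At a minimum of 1 RPKM it had 1.95 ± 0.543 RPKM in old and 5.07 ± 1.71 RPKM in young animals and a log2 fold change of -1.52 on library totals (adjusted p = 0.00214). Cdkn2a had 6 reads in all old and 11 in all young libraries and was not tested. Of the genes excluded by the sort, Pecam1 (CD31) was measured at 12.5 ± 5.70 in old against 12.9 ± 2.13 RPKM in young animals, with a log2 fold change of -0.11 on the deposited scale and -0.75 ± 0.26 on library totals (adjusted p = 0.0574). Ly6a (Sca1) had 19.2 ± 8.96 against 16.2 ± 3.43 RPKM, with 0.14 on the deposited scale and -0.52 ± 0.34 on library totals (adjusted p = 0.294). Ptprc (CD45), not tested, had 0.241 ± 0.164 against 1.04 ± 0.517 RPKM.

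Of the 38 lists tested, camera called 17, 5 higher and 12 lower in old animals relative to the other genes. None was called with a correlation estimated from the data, where 0 lists had even an unadjusted p under 0.05 and the smallest adjusted p was 0.65. Fry, which asks whether members move on balance in one direction, called 24 on the deposited scale and 14 on library totals. All its calls on the deposited scale were higher, as is the median of all tested genes (0.64). They include collagens (fry adjusted p = 0.0402), which camera ranked lower. On library totals its calls went both ways, with the smallest adjusted p for muscle stem cell identity (0.00495, lower). There fry did not call immediate early genes (adjusted p = 0.0950) or endothelial markers (0.191).

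Interferon-stimulated genes ranked higher (camera, adjusted p = 0.000266, and adjusted p = 0.65 with an estimated correlation). On library totals 11 of 27 measured members rose, 1 fell and 15 were not called. When adjusted over the list alone, 12 rose and 1 fell. The antiviral Ifit3 rose by 1.28 ± 0.22, the GTPase Igtp by 0.97 ± 0.11 and the chaperone Rtp4 by 0.91 ± 0.17. Genes of MHC class I antigen presentation ranked higher (camera, adjusted p = 0.0325, and adjusted p = 0.833 with an estimated correlation), with 6 of 20 risen, 0 fallen and 14 not called. Adjusted over the list alone, 6 rose and 1 fell. At an unadjusted p under 0.05, 11 members were higher and 2 lower. The peptide-loading genes Tapbp and Tapbpl rose by 0.54 ± 0.12 and 0.61 ± 0.16, and the immunoproteasome subunit Psmb8 had 0.46 ± 0.19 (adjusted p = 0.092). Without young libraries 1 and 2 the MHC class I list had an adjusted p of 0.0664 and Tapbpl, on library totals, of 0.0590. The list had 0.0524 with the trend over expression level removed, and was lost with 2 of the 8 libraries left out in turn, with a highest adjusted p of 0.103 without young library 1.

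Secreted factors associated with senescence ranked higher (camera, adjusted p = 0.0325, and adjusted p = 0.797 with an estimated correlation). Of 28 measured members 6 rose, 1 fell and 21 were not called. Among its members adjusted over the list alone, 9 rose and 1 fell. Besides Mmp3, the chemokine Ccl11 rose by 1.38 ± 0.14 on library totals (2.07 on the deposited scale, with 368 RPKM in old and 86.5 in young animals), and the protease inhibitor Serpine2 by 1.25 ± 0.12. Tenocyte markers (6 of 7) rose in the same libraries. Mmp3 was lowest among old animals in library 2 (72.5 RPKM), as was the tenocyte sum (3863 CPM). The fibroblast, pericyte, muscle fibre and erythroid sums were lowest there too, so this is not particular to tenocyte markers. Of 13 fibroblast markers 4 rose, among them Fbln1 and Mfap4, while 2 fell and 7 were not called. Mfap4 lost its call with 4 of the 8 libraries left out in turn. Genes of the unfolded protein and integrated stress response ranked higher (camera, adjusted p = 0.024, and adjusted p = 0.833 with an estimated correlation), with 8 of 25 risen, 0 fallen and 17 not called. With members adjusted over the list alone, 10 rose. At an unadjusted p under 0.05, 12 were higher and 0 lower. The endoplasmic reticulum protein Creld2 rose by 0.85 ± 0.16, the folate enzyme Mthfd2 by 0.70 ± 0.12 and the pseudokinase Trib3 by 0.55 ± 0.17. Trib3 was not called on library totals with 6 of the 8 libraries left out in turn, with a highest adjusted p of 0.0924 without old library 4, nor with reads thinned to equal totals (adjusted p = 0.173). Without young libraries 1 and 2 each of these 2 lists had an adjusted p of 0.0516. The stress response list had 0.0876 with the trend over expression level removed, and the senescence list was lost with 3 of the 8 libraries left out in turn, with a highest adjusted p of 0.102 without young library 1.

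NRF2 target and antioxidant genes were not called on the deposited scale (camera, adjusted p = 0.0641, and adjusted p = 0.905 with an estimated correlation) and ranked higher on library totals (adjusted p = 0.0115, and adjusted p = 0.538 with an estimated correlation). In this list 12 of 27 members rose, 4 fell and 11 were not called. When adjusted over the list alone, 14 rose and 4 fell. On the deposited scale the list was called with 3 of the 8 libraries left out in turn, with a lowest adjusted p of 0.0381 without young library 4. It was also called there with limma-voom (adjusted p = 0.0384). Thioredoxin reductase Txnrd1 rose by 1.07 ± 0.12 and Gclc, the rate-limiting enzyme of glutathione synthesis, by 0.91 ± 0.20, beside Hmox1. The wider list of glutathione metabolism was not called (camera, adjusted p = 0.294, and adjusted p = 0.933 with an estimated correlation), with 7 of 26 members risen, 2 fallen and 17 not called. Adjusted over the list alone, 9 rose and 4 fell.

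Immediate early and dissociation response genes ranked lower (camera, adjusted p = 2.13e-07, and adjusted p = 0.65 with an estimated correlation, medians 0.05 on the deposited scale and -0.64 on library totals). On library totals 12 of 28 fell, 1 rose and 15 were not called. Among its members adjusted over the list alone, 13 fell and 1 rose. Atf3 fell by 1.21 ± 0.22 while Fosl1 rose by 0.91 ± 0.14, and Ier3 (0.16 ± 0.22) and Nr4a2 (0.07 ± 0.24) were not called. On the deposited scale 6 members were higher and 0 lower. Quiescence-associated genes ranked lower (camera, adjusted p = 4.01e-05, and adjusted p = 0.65 with an estimated correlation, medians 0.23 on the deposited scale and -0.44 on library totals), with 7 of 16 fallen, 0 risen and 9 not called. With members adjusted over the list alone, 8 fell. Beside Calcr, the Notch target Hey1 fell by 1.03 ± 0.15, and Bmp4 (-0.02 ± 0.15) was not called.

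Myogenic commitment factors ranked lower on the deposited scale (camera, adjusted p = 0.0012, and adjusted p = 0.65 with an estimated correlation, medians 0.11 on the deposited scale and -0.50 on library totals), with 6 of 12 fallen, 1 risen and 5 not called. When adjusted over the list alone, 6 fell and 2 rose. On library totals the list was not called (adjusted p = 0.0581). The member that rose was Myod1. Myogenin, Myog, chosen after its values were seen, fell by 2.11 ± 0.41 on library totals and by 1.60 on the deposited scale, where it had 2.18 ± 1.26 RPKM in old and 9.62 ± 6.61 in young animals. The acetylcholine receptor partner Rapsn fell by 0.93 ± 0.14 and the slow troponin Tnnt1 by 0.75 ± 0.13, and Musk (0.68 ± 0.25) and Mef2d (0.30 ± 0.13) were not called. Mature muscle fibre genes ranked lower in the same libraries (camera, adjusted p = 1.40e-05, and adjusted p = 0.65 with an estimated correlation), with a median of 0.09 on the deposited scale and -0.55 on library totals. Muscle stem cell identity genes were not called (camera, adjusted p = 0.0556, and adjusted p = 0.833 with an estimated correlation, medians 0.54 on the deposited scale and -0.15 on library totals), with 6 of 18 fallen, 1 risen and 11 not called. The counts of 6 and 1 stayed the same when adjusted over the list alone. Fry called the identity list higher on the deposited scale (adjusted p = 0.0418) and lower on library totals (adjusted p = 0.00495). The receptor Fgfr4 fell by 0.86 ± 0.10 and dystroglycan, Dag1, by 1.47 ± 0.18, and Met had 0.28 ± 0.14 without a call. The identity list was called lower with the trend over expression level removed (adjusted p = 0.0183), with subtracted signal (0.0345), without young libraries 1 and 2 (0.0456) and with 3 of the 8 libraries left out in turn, with a lowest adjusted p of 0.0370 without young library 2. Notch signalling genes were not called on the deposited scale (camera, adjusted p = 0.103, and adjusted p = 0.833 with an estimated correlation, medians 0.39 on the deposited scale and -0.24 on library totals) and ranked lower on library totals (adjusted p = 0.046, and adjusted p = 0.599 with an estimated correlation), with 4 of 14 fallen, 0 risen and 10 not called. Adjusted over the list alone, 4 fell. The protease Adam10 fell by 0.43 ± 0.11 as a share of reads against a log2 fold change of 0.20 on the deposited scale, with an adjusted p of 0.0564 without old library 2 and of 0.111 with thinned reads, and Snw1 (0.24 ± 0.15), Notch1 (0.04 ± 0.12) and Jag1 (0.07 ± 0.21) were not called. Cyclins, their kinases and inhibitors ranked lower on the deposited scale (camera, adjusted p = 0.0399, and adjusted p = 0.797 with an estimated correlation, medians 0.14 on the deposited scale and -0.52 on library totals), with 3 of 6 fallen, 0 risen and 3 not called. Among its members adjusted over the list alone, 4 fell and 1 rose. The cyclin list was not called on library totals (adjusted p = 0.0773), and on the deposited scale it was lost with 6 of the 8 libraries left out in turn, with a highest adjusted p of 0.0975 without young library 3. The members that fell were Cdk2 (-0.66 ± 0.13), Ccnd3 (-0.71 ± 0.19) and Cdk4 (-0.40 ± 0.11, and 0.28 on the deposited scale), while Trp53 had 0.40 ± 0.16 without a call. With 3 of the 8 libraries left out in turn Ccnd3 and Cdk4 were each no longer called, with highest adjusted p-values of 0.061 without young library 3 and 0.0586 without young library 4.

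Collagens and extracellular matrix genes ranked lower (camera, adjusted p = 0.000597, and adjusted p = 0.797 with an estimated correlation, medians 0.32 on the deposited scale and -0.33 on library totals), with members on both sides. Of 35 measured genes 11 fell, 5 rose and 19 were not called. With members adjusted over the list alone, 15 fell and 5 rose. On the deposited scale 13 members were higher and 4 lower. Beside Col3a1 and Col15a1, which fell, the cross-linking enzyme Lox rose by 1.47 ± 0.22, tenascin Tnc by 1.35 ± 0.22 and Col8a1 by 1.10 ± 0.27. Tenocyte markers (6 of 7) rose in the same libraries. Of 13 fibroblast markers 4 rose, 2 fell and 7 were not called. Lox and Dcn, which rose, and Col1a1 and Col3a1, which fell, are members of both the fibroblast and the collagen list. Cholesterol synthesis genes ranked lower (camera, adjusted p = 1.90e-05, and adjusted p = 0.705 with an estimated correlation, medians 0.10 on the deposited scale and -0.53 on library totals), with 8 of 16 fallen, 0 risen and 8 not called. When adjusted over the list alone, 10 fell. Hmgcs1, an early enzyme of the pathway, fell by 0.95 ± 0.17 and Nsdhl by 0.74 ± 0.14, and Ebp (0.23 ± 0.12), Pmvk (-0.21 ± 0.15) and the regulator Srebf2 (-0.27 ± 0.14) were not called. Fatty acid oxidation genes ranked lower (camera, adjusted p = 0.0372, and adjusted p = 0.833 with an estimated correlation, medians 0.41 on the deposited scale and -0.26 on library totals), with 6 of 17 fallen, 1 risen and 10 not called. Adjusted over the list alone, 6 fell and 1 rose. The hydratase Echs1 fell by 0.91 ± 0.14 while the acyl-CoA synthetase Acsl4 rose by 1.31 ± 0.14, and Acsl3 (0.18 ± 0.16) and Acadvl (0.19 ± 0.17) were not called. The fatty acid oxidation list was lost with 4 of the 8 libraries left out in turn, with a highest adjusted p of 0.120 without young library 4.

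Nuclear-encoded subunits of oxidative phosphorylation were not called on the deposited scale (camera, adjusted p = 0.106, and adjusted p = 0.933 with an estimated correlation, medians 0.49 on the deposited scale and -0.15 on library totals) and ranked lower on library totals (adjusted p = 0.0056, and adjusted p = 0.599 with an estimated correlation). Of 68 members 10 fell, 1 rose and 57 were not called. Among its members adjusted over the list alone, 9 fell and 1 rose. Ndufv3 fell by 1.00 ± 0.18 and Ndufs8 by 0.67 ± 0.12 (0.01 on the deposited scale), cytochrome c (Cycs) rose by 0.54 ± 0.13, and Cox7a2 (0.37 ± 0.13) and Cox5a (0.27 ± 0.15) were not called. With reads thinned to equal totals Cycs was not called (adjusted p = 0.0560), nor without young libraries 1 and 2 (adjusted p = 0.0611). On the deposited scale the oxidative phosphorylation list was called without old library 2 (adjusted p = 0.0122) and with limma-voom (adjusted p = 0.0399). Heat shock proteins and chaperones ranked lower on the deposited scale (camera, adjusted p = 0.0135, and adjusted p = 0.833 with an estimated correlation) and were not called on library totals (adjusted p = 0.434). On library totals 6 of 28 fell, 3 rose and 19 were not called, with the same counts of 6 and 3 when adjusted over the list alone. On the deposited scale 16 members were higher and 3 lower. The median of the heat shock list was 0.62 on the deposited scale and -0.05 on library totals. Hspa9 rose by 0.60 ± 0.12, Dnaja2 by 0.45 ± 0.13 and Cct5 by 0.49 ± 0.15, and Dnajb4 fell by 0.61 ± 0.13 as a share of reads (0.06 on the deposited scale). The inducible HSP70 genes Hspa1b (-2.01 ± 0.50) and Hspa1a (-1.76 ± 0.48) and their cochaperone Dnajb1 (-1.71 ± 0.42) fell and were chosen after their values were seen. Hspa1a was not called with 2 of the 8 libraries left out in turn, with a highest adjusted p of 0.0662 without old library 4. Dnaja2 was not called with 3 and Cct5 with 6 of the 8 libraries left out in turn, with highest adjusted p-values of 0.0691 without young library 1 and 0.0841 without old library 2. The heat shock list had an adjusted p of 0.0516 without young libraries 1 and 2 and of 0.0506 without old library 4. Hspa1b was not called on library totals without young libraries 1 and 2 (adjusted p = 0.0646).

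**Figure D4:**
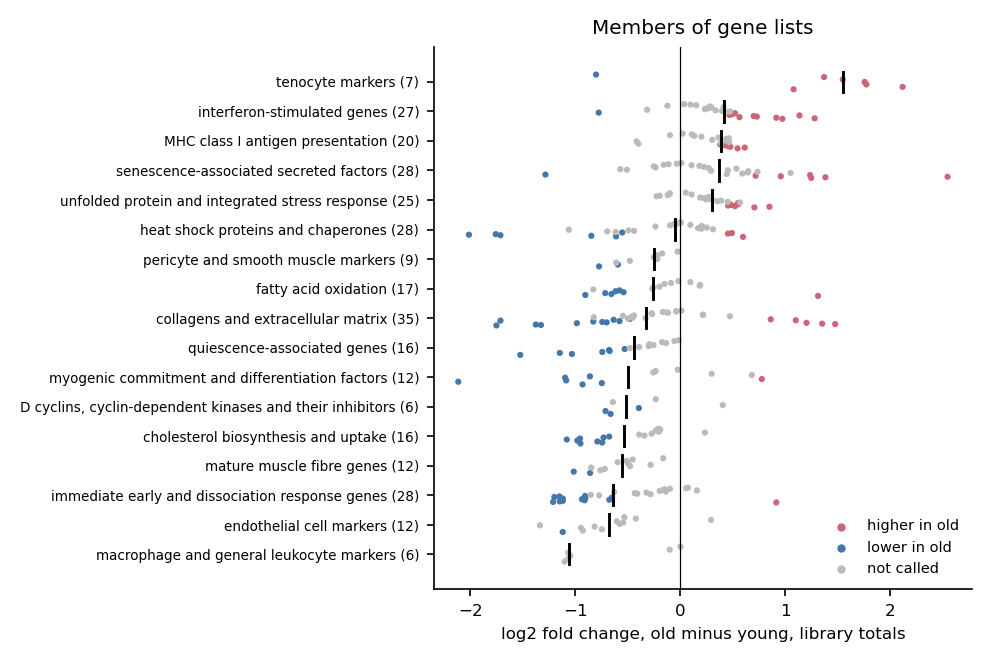
Each point is a measured member of 1 of the 17 gene lists called on the deposited scale, with the log2 fold change on library totals on the x axis, red for genes higher in old animals, blue for lower and grey for not called, and a black bar at the list median. Medians run from -1.06 for macrophage and leukocyte markers to 1.55 for tenocyte markers, those of the 12 lower lists lie between -0.43 and 0.62 on the deposited scale, and no list was called with an estimated correlation, where the smallest adjusted p was 0.65.

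The remaining programme lists were not called by camera on either scale with all libraries. Cytosolic ribosomal proteins had 78 of 78 members higher on the deposited scale and 0 called on library totals by limma, also with 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Their list adjusted p was 0.156, and adjusted p = 0.933 with an estimated correlation, and their medians were 0.73 and 0.05 on the 2 scales. On the deposited scale the ribosomal list was called higher without young library 2 (adjusted p = 0.0139) and with limma-voom (adjusted p = 0.0483). Messenger RNAs of the mitochondrial genome had 0 of 7 called on library totals by limma, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (list adjusted p = 0.635, and adjusted p = 0.933 with an estimated correlation). In the p53 target list 2 of 15 rose, 5 fell and 8 were not called, and 3 rose and 5 fell when adjusted over the list alone (list adjusted p = 0.481, and adjusted p = 0.933 with an estimated correlation). Autophagy and lysosome genes had 1 of 36 risen, 3 fallen and 32 not called, with the same counts of 1 and 3 when adjusted over the list alone (list adjusted p = 0.438, and adjusted p = 0.933 with an estimated correlation). Glycolysis genes had 2 of 23 risen, 2 fallen and 19 not called, with 2 and 2 when adjusted over the list alone (list adjusted p = 0.897 in the lower direction, and adjusted p = 0.955 with an estimated correlation), with a median of 0.05 and a mean of -0.01 on library totals. Circadian clock genes had 1 of 13 risen, 4 fallen and 8 not called, and 2 and 4 when adjusted over the list alone (list adjusted p = 0.781, and adjusted p = 0.943 with an estimated correlation). Complement and coagulation factors had 2 of 12 risen, 2 fallen and 8 not called, and 3 and 3 when adjusted over the list alone (list adjusted p = 0.592 in the lower direction, and adjusted p = 0.933 with an estimated correlation), with a median of 0.16 and a mean of -0.05 on library totals.

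Signalling lists other than Notch were not called by camera on either scale. TGF-beta, activin and BMP signalling had 3 of 28 risen, 3 fallen and 22 not called, with 3 and 3 when adjusted over the list alone (camera, adjusted p = 0.897 in the higher direction, and adjusted p = 0.955 with an estimated correlation), with a median of -0.06 on library totals. JAK-STAT and p38 signalling had 2 of 18 risen, 1 fallen and 15 not called, and 1 and 0 when adjusted over the list alone (adjusted p = 0.897 in the higher direction, and adjusted p = 0.955 with an estimated correlation), with a median of 0.08 and a mean of -0.00 on library totals. Wnt signalling had 2 of 7 risen, 1 fallen and 4 not called, and 3 and 1 when adjusted over the list alone (adjusted p = 0.294, and adjusted p = 0.833 with an estimated correlation). Its medians were 1.02 on the deposited scale and 0.43 on library totals, and fry gave adjusted p = 0.00153 and 0.167. FGF receptor signalling had 0 of 10 risen, 2 fallen and 8 not called, and 0 and 1 when adjusted over the list alone (adjusted p = 0.451, and adjusted p = 0.933 with an estimated correlation). Its medians were 0.48 on the deposited scale and -0.18 on library totals, and fry called it higher on the first (adjusted p = 0.0218) and lower on the second (adjusted p = 0.0423). Chromatin modifiers had 1 of 22 risen, 1 fallen and 20 not called, with 1 and 1 when adjusted over the list alone (adjusted p = 0.586, and adjusted p = 0.933 with an estimated correlation). S phase and mitosis genes had 1 of 7 risen, 0 fallen and 6 not called, and 0 when adjusted over the list alone (adjusted p = 0.735, and adjusted p = 0.937 with an estimated correlation), and 7 of the 36 listed genes were measured. Hox cluster genes, with 1 measured member, and lymphocyte markers, with 0, were not tested as lists.

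Markers of cells that the sort should exclude were examined as lists and as sums. A few of them are also members of the stem cell lists. Chodl (tenocyte), Des (pericyte) and Erbb3 (Schwann) are in the identity list, and Rgs5 (pericyte) is in the quiescence list. Signal of these genes alone thus does not mark other cells. Tenocyte markers ranked higher in old animals (camera, adjusted p = 0.000552, and adjusted p = 0.65 with an estimated correlation), with 6 of 7 risen, 1 fallen and 0 not called. The counts of 6 and 1 stayed the same when adjusted over the list alone. Beside Thbs4, the matrix protein Comp rose by 1.75 ± 0.33 and the transcription factor Mkx by 1.08 ± 0.15. Endothelial markers ranked lower (camera, adjusted p = 6.23e-07, and adjusted p = 0.65 with an estimated correlation), with 1 of 12 fallen, 0 risen and 11 not called. With members adjusted over the list alone, 5 fell. The member that fell was Ly6c1 (-1.12 ± 0.35), which was not called with 5 of the 8 libraries left out in turn, with a highest adjusted p of 0.105 without old library 4, and Cdh5 (-0.93 ± 0.32), Plvap (-1.34 ± 0.54) and Cav1 (0.29 ± 0.16) were not called. Mature muscle fibre genes ranked lower (camera, adjusted p = 1.40e-05, and adjusted p = 0.65 with an estimated correlation, medians 0.09 on the deposited scale and -0.55 on library totals), with 2 of 12 fallen, 0 risen and 10 not called. When adjusted over the list alone, 2 fell. These were Actn3 (-0.86 ± 0.14) and Atp2a1 (-1.02 ± 0.26), while Tpm1 and Tpm2 had -0.28 ± 0.22 and -0.16 ± 0.21. Atp2a1 was not called on library totals without young libraries 1 and 2 (adjusted p = 0.0572). Without old library 2 the fibre list had an adjusted p of 0.0547.

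Macrophage and leukocyte markers ranked lower on the deposited scale (camera, adjusted p = 0.000552, and adjusted p = 0.65 with an estimated correlation), although 0 of 6 members were called by limma on library totals or when adjusted over the list alone, with 1 at an unadjusted p under 0.05. The list was not called on library totals (adjusted p = 0.204). Cd74 had -1.10 ± 0.48, H2-Eb1 -1.07 ± 0.49, Lyz2 -0.10 ± 0.44 and Cd68 0.00 ± 0.18. Pericyte and smooth muscle markers ranked lower on the deposited scale (camera, adjusted p = 0.0293, and adjusted p = 0.828 with an estimated correlation, medians 0.35 on the deposited scale and -0.25 on library totals), with 2 of 9 fallen, 0 risen and 7 not called. Adjusted over the list alone, 2 fell. These were Acta2 (-0.77 ± 0.19) and Mcam (-0.59 ± 0.19), the latter not called with 5 of the 8 libraries left out in turn, with a highest adjusted p of 0.111 without old library 2 and 0.103 with thinned reads, while Des, Rgs5 and Pdgfrb had -0.22, -0.17 and -0.03. The pericyte list was not called on library totals (adjusted p = 0.0988). On the deposited scale it was lost with 3 of the 8 libraries left out in turn, with a highest adjusted p of 0.298 without old library 2, and had 0.225 without young libraries 1 and 2. Fibroblast markers were not called (camera, adjusted p = 0.322, and adjusted p = 0.905 with an estimated correlation, medians 0.43 on the deposited scale and -0.25 on library totals), with 4 of 13 risen, 2 fallen and 7 not called, and 4 and 2 when adjusted over the list alone. Fbln1 rose by 1.11 ± 0.28 and Mfap4 by 0.99 ± 0.31, and Mfap4 was not called with 4 of the 8 libraries left out in turn, with a highest adjusted p of 0.0991 without young library 3. Schwann cell markers were not called (adjusted p = 0.294, and adjusted p = 0.883 with an estimated correlation, medians 0.26 on the deposited scale and -0.32 on library totals), with 1 of 5 fallen, 0 risen and 4 not called. Among its members adjusted over the list alone, 1 fell. Pmp22 fell by 0.60 ± 0.16 as a share of reads (0.09 on the deposited scale), with an adjusted p of 0.0536 without young library 3, and Mbp had -0.10. Erythroid genes had 0 of 4 called by limma, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (list adjusted p = 0.207, and adjusted p = 0.833 with an estimated correlation). Without old library 3, which had the highest erythroid sum, the list was called lower (adjusted p = 0.0102).

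Summed over their markers, 0 of the 9 cell types passed the exact permutation test after Benjamini-Hochberg adjustment, with 4 at an unadjusted p under 0.05 on the deposited scale and 1 on library totals. The smallest p the 70 assignments can give is 0.0286. On the deposited scale tenocyte markers summed to 5294 ± 1631 CPM in old and 1955 ± 516 in young animals (log2 difference 1.43, exact permutation p = 0.0286, adjusted p = 0.0643). On library totals they summed to 4237 ± 1581 and 2440 ± 372 CPM (difference 0.73, exact permutation adjusted p = 0.257). Endothelial markers summed to 1825 ± 209 and 1242 ± 118 CPM on the deposited scale (log2 difference 0.55 with adjusted p = 0.0643 by the exact test). Scaled by library totals, the endothelial sums were 1433 ± 147 in old and 1598 ± 309 in young animals (difference -0.14). Lymphocyte markers summed to 27.3 ± 10.0 and 45.6 ± 10.2 CPM (log2 difference -0.78, and -1.45 on library totals). Theirs is the sum with an unadjusted p under 0.05 on library totals (exact permutation p = 0.0286, adjusted p = 0.257). Silent gene families also stood higher in young libraries (0.348 against 0.0347 RPKM). Young library 2, highest for these families (0.583 RPKM), also had the highest lymphocyte sum (58.2 CPM). Whether low-level signal gives this difference was not tested. Pericyte markers had a log2 difference of 0.39 and of -0.30 on library totals.

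Depth and age coincide in these libraries, since each of the 4 young libraries holds fewer reads in genes than each of the 4 old. The labels state 26 to 37 M reads per library, so this need not be a difference in sequencing. The source of the low-level reads in the young libraries is not settled. Spike-in scaling per cell is not analysed here, so a fold change is a change in the share of reads, not in RNA per cell, and the number of lists called is not told apart from chance, since 7 of the 35 splits of the libraries, the real one included, gave at least 17.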

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

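The tests of abundant tendon transcripts and of other splits of the libraries for gene counts were chosen after seeing the result, and the other tests had their predictions written before their values were seen. The decision rule of the X chromosome test was changed once after its value was seen, from the interval to the ratio, and then changed back. The test of the scaling took the place of an earlier one whose outcome was fixed, since factors set over the tested genes centre those genes by construction.

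Low-level reads in silent gene families stood at 0.348 ± 0.169 RPKM in the young and 0.0347 ± 0.0109 RPKM in the old libraries. Old reads thinned to the young totals gave 0.0352 RPKM, under the 0.1 set as the limit beforehand. Random thinning keeps the expected mean RPKM, so a value near that of the full old libraries was fixed in advance. The test therefore draws no conclusion on depth. Genomic DNA carried into the young libraries is a possible explanation, and a male carries a single X chromosome against paired autosomes. Among genes with 0 reads in all old libraries the X-linked genes had 0.477 times the mean young RPKM of the autosomal genes (95% bootstrap interval 0.344 to 0.625). The ratio lies inside the predicted range of 0.35 to 0.65 but its interval reaches below it, so the test leaves genomic DNA open. The single young libraries gave ratios of 0.410 to 0.561. The ratio set beforehand as speaking against genomic DNA lies above the whole interval, so that contrary prediction was not met.

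Most expressed genes stood higher in old animals on the deposited scale, with a median log2 fold change of 0.64. Scaling factors set over all genes, those with low-level reads included, could account for this. With the silent-gene signal subtracted and TMM factors set again over all genes the median was 0.291, between the limits of 0.2 and 0.4 set beforehand. With every library thinned to the smallest total it was 0.367, also between these limits. Neither the scaling nor the depth is thereby excluded or shown to be the cause, and a rise in messenger RNA per cell would need the spike-in, not analysed here.

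Tenocyte markers were higher in old animals, and more tendon cells in the old sorts could account for this. Of 7 abundant tendon cell transcripts Col1a1, Col3a1 and Sparc fell and Dcn rose on library totals, with a median log2 fold change of -0.825. Col1a2 (-0.83) and Lum (-0.44) were also below 0 without a call, and Bgn had 0.01. The prediction against tendon cells asked for at least 4 of them to fall past the threshold, so the test does not decide between a change in the cells and a change in the sort. With reads thinned to equal totals 6 of the 7 measured tenocyte markers were still higher, so their calls do not need the larger read number. Thinning keeps each gene's expected share of reads. It therefore cannot exclude another effect that coincides with depth.

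For the number of genes, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave 3946 on the deposited scale. The highest other count was 1. On library totals the real split was likewise the only 1 of 35 to reach its count, with 1422 genes and 2 as the highest other count. A share of 1 in 35 is the smallest that these splits can give. The real split also parts the libraries by depth, so these counts cannot tell age from depth. Chance cannot be excluded for the number of lists, since 7 of the 35 splits, the real one included, gave at least 17 and the highest other count was 21.

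A single library lay far from the other 3 of its group in 19 of 264 groups tested, which is 7.20%, where chance alone gives 5%, about 1 in 20 groups. The value given for each is the gap to the nearest library over the range of the group. Old library 3 was highest for the erythroid genes Hbb-b1 (0.848), Hba-a1 (0.903), Hba-a2 (0.857) and Alas2 (0.93) and for the erythroid sum (0.879). Old library 2 was lowest for Angptl7 (0.937, 151 RPKM against 455 to 475) and highest for Acsl4 (0.854) and Dnaja2 (0.958). Old library 1 was highest for Cdkn2a (0.85) and Actn3 (0.934) and lowest for Adam10 (0.847), and old library 4 was lowest for Pmp22 (0.908). Young library 2 was lowest for Acadvl (0.857), Dnajb4 (0.91) and the pericyte sum (0.844). Young library 3 was highest for Lyz2 (0.913, 40.7 RPKM against 9.33 to 12.0) and Acsl3 (0.907). Young library 4 was highest for Dio2 (0.882), and young library 1 was lowest for Rtp4 (0.862).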

How the results depend on the processing

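The tests with TMM over the tested genes, the limits of 1 and 10 RPKM, pseudocounts, library weights, subtracted silent-gene signal, thinned reads, removal of the trend over expression level and libraries 1 and 2 of the young group left out were chosen after seeing the data, as were all pairs of a setting with library totals. Quasi-likelihood and negative-binomial count tests were not run because the unit is RPKM, and the spike-in scaling and spike-in share were not run because the table has 0 ERCC sequences. Depth limits the young libraries, where 3 reads in a gene of 1 kb correspond to 0.403 to 0.959 RPKM.

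Of 3946 genes past the threshold on the deposited scale, 3882 higher and 64 lower, the count was 1422 on library totals (700 higher, 722 lower) and 1428 with TMM over the tested genes (690 and 738). It was 1435 with limma-voom on library totals (692 and 743), 1377 with subtracted signal and library totals (814 and 563) and 1089 with thinned reads on library totals (549 and 540). Without young libraries 1 and 2 it was 1033 on library totals (475 and 558). All of these use library totals or TMM over the tested genes, and it is this scaling that takes off the shift of 0.64 by construction. Without a filter 11513 genes passed, 6908 of them lower. The count was 1016 at an absolute log2 fold change of at least 1 (996 and 20) and 2585 against a fold of 1.2 (2557 and 28), both of which ask for larger changes. The lower genes alone were 593 with at least 5 CPM in 4 libraries, 592 and 24 with mean limits of 1 and 10 RPKM, 117 with library weights, 122 without young libraries 1 and 2 and 31 at adjusted p under 0.01. For these the cause was not tested. Leaving out each library gave 3488 to 4101 genes on the deposited scale, 3442 to 4048 higher and 44 to 129 lower, and 1005 to 1616 on library totals. The other settings kept the total within 1.5 times of 3946.

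The count of 17 lists was 27 without a filter, 10 without young libraries 1 and 2 on library totals and 0 with an estimated correlation on either scale, and the cause was not tested. Leaving out each library gave 12 to 19 lists. With the trend over expression level removed 18 lists were called, without the stress response (adjusted p = 0.0876) and MHC class I (0.0524) lists and with muscle stem cell identity (0.0183), oxidative phosphorylation (0.0203) and NRF2 targets (0.0495). All other settings stayed within 1.5 times of 17. Without a filter 9 lists turned in direction, with adjusted p-values of cyclins 0.298, cholesterol synthesis 0.643, collagens 0.00686, fatty acid oxidation 0.0268, heat shock proteins 0.00172, immediate early genes 0.111, myogenic factors 0.958, pericyte markers 0.117 and quiescence-associated genes 0.124, and the cause was not tested.

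Of the 74 named genes called on library totals, 62 kept the call whichever library was left out, 12 lost it without at least 1, and 0 changed sign. Without young libraries 1 and 2, 15 lost it, with thinned reads 4, with limma-voom 3 and with subtracted signal 1.

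Named genes that changed sign on library totals, and with TMM factors set over the tested genes, have both log2 fold changes given in that order. Spry1 had -0.30 and -0.30, and Cdkn1a -0.23 and -0.24. Ly6a had -0.52 and -0.52, and Cdk4 -0.40 and -0.40. Mbp had -0.10 and -0.10, and Srebf2 -0.27 and -0.28. Pmvk had -0.21 and -0.21, and Hbb-b1 -0.31 and -0.31. Hba-a1 had -0.16 and -0.16, and Lyz2 -0.10 and -0.10. Tpm1 had -0.28 and -0.29, and Tpm2 -0.16 and -0.17. Des had -0.22 and -0.22, and Rgs5 -0.17 and -0.18. Pdgfrb had -0.0266 and -0.0295, and Bmp4 -0.0171 and -0.0195. Adam10 had -0.43 and -0.44, and Pmp22 -0.60 and -0.61. Hba-a2 had -0.36 and -0.36, and Dnajb4 -0.61 and -0.61. Ndufs8 had -0.67 and -0.67. Cd68 changed sign only with the latter, to -0.00238. Both settings centre the tested genes near 0, which takes the shift of 0.64 off each gene by construction. 

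Other changes of sign, whose cause was not tested, were as follows. With the silent-gene signal subtracted, the log2 fold changes were Pax7 0.00449, Cdk2 0.00804 and Mcam 0.0580. Without young libraries 1 and 2, the log2 fold changes were Lyz2 -0.0300, Pmp22 -0.16, Dnajb4 -0.12, Ndufs8 -0.19 and Mcam 0.0102. With median-ratio scaling, the log2 fold changes were Pmp22 -0.000905, Dnajb4 -0.0289 and Ndufs8 -0.0786. With library weights, the log2 fold changes were Pmp22 -0.00755, Dnajb4 -0.12, Ndufs8 -0.12 and Mcam 0.00853. With limma-voom and TMM, that of Ndufs8 was -0.0195. Leaving out each library in turn gave log2 fold changes on both sides of 0. Pax7 ranged from -0.18 to 0.14, and Pecam1 from -0.36 to 0.0564. Ly6a ranged from -0.0625 to 0.36, and Hbb-b1 from -0.0780 to 0.64. Cdk2 ranged from -0.17 to 0.0506, and Ccnd3 from -0.25 to 0.0109. Pmp22 ranged from -0.0853 to 0.23, and Hba-a2 from -0.23 to 0.52. Dnajb4 ranged from -0.11 to 0.17, and Ndufs8 from -0.12 to 0.13. Acta2 ranged from -0.27 to 0.10, and Mcam from -0.100 to 0.0783.

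The log2 differences of summed markers changed sign as follows. On library totals, they were endothelial -0.14, fibroblast -0.15, pericyte -0.30, Schwann -0.43, muscle fibre -0.69 and erythroid -0.29. As the median of the markers, they were endothelial -0.28 and muscle fibre -0.16. Leaving out each library gave -0.23 to 0.30 for the muscle fibre sum and -0.0491 to 0.63 for the erythroid sum. Library totals take off the shift by construction, and the other causes were not tested.

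With the replicate number as a block 3625 genes passed on the deposited scale (3559 higher, 66 lower) and 1299 on library totals (637 and 662), and 12 and 17 lists. The lists no longer called were the stress response and pericyte lists (adjusted p = 0.0697 each), cyclins (0.0731), fatty acid oxidation (0.0756) and MHC class I (0.0776). Of the named genes called on library totals 3 were no longer called, Ly6c1 (0.0672), Cct5 (0.0610) and Mcam (0.0939). The numbers do not pair the libraries, since the deviations of same-numbered libraries correlate at -0.17, -0.09, 0.39 and -0.24, and 1 of the 4 numbers correlates best with its own.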

Other observations

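The gene groups in these observations were chosen after seeing the data, so their tests rank genes that had already drawn attention.

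The 39 measured ribosome assembly genes hold RNA polymerase I subunits, which transcribe ribosomal RNA, beside genes that process it in the nucleolus. Of these 39 genes 25 rose on library totals, 0 fell and 14 were not called (limma, Benjamini-Hochberg). Their median log2 fold change was 0.59. The methyltransferase Nop2 rose by 1.24 ± 0.15, Rrp1b by 1.29 ± 0.17, the polymerase I subunit Polr1b by 1.17 ± 0.18 and the snoRNP protein Nop56 by 0.86 ± 0.16. The list had an unadjusted p of 1.01e-13 by camera, 0.0626 with an estimated correlation and 0.00104 by fry. Of the 35 splits of the libraries the real one gave the smallest camera p, but another gave 7.82e-13, so the camera p alone does not set the real grouping apart. Cytosolic ribosomal proteins, by contrast, had 0 of 78 members called on library totals.

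Of 593 Reactome pathways 14 passed on library totals (camera, adjusted p under 0.05), 8 higher and 6 lower, and 0 passed with an estimated correlation (adjusted p = 0.968). In mRNA splicing 18 of 99 genes rose and 2 fell (adjusted p = 0.0151), and in snRNP assembly 7 of 18 rose and 0 fell (adjusted p = 0.0197). In mitochondrial fatty acid beta-oxidation 7 of 11 fell and 0 rose (adjusted p = 0.0151), in peroxisomal lipid metabolism 8 of 11 fell and 1 rose (adjusted p = 0.0308), and in collagen biosynthesis 7 of 21 fell and 1 rose (adjusted p = 0.0308). Each had an adjusted p of 0.968 with an estimated correlation. The Reactome set of the antiviral mechanism by interferon-stimulated genes was not called (camera, adjusted p = 0.627, and adjusted p = 0.968 with an estimated correlation). In it 4 of 19 rose and 2 fell, with a median of 0.09. The Reactome set of the senescence-associated secretory phenotype was not called and lay in the lower direction (adjusted p = 0.399, and adjusted p = 0.968 with an estimated correlation), with 1 of 21 risen and 5 fallen, opposite to the list of secreted factors fixed beforehand. Among microRNA genes 11 of 38 tested fell on library totals and 0 rose, beside 722 of all 5703 genes. Among genes shorter than 200 bp 12 of 60 fell and 2 rose. A single read in a gene of 1 kb is worth 0.134 to 0.320 RPKM in the young libraries, and more in a shorter gene. Short genes can thus pass the filter of 5 RPKM on few reads. Low-level signal was also higher in young libraries (0.348 against 0.0347 RPKM in silent families), so these falls are not told apart from it.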
